A study of Mus musculus with 16 samples.

How the data were processed

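The values used are the deposited log2 values, made by the authors with GCRMA (background correction, quantile normalization and 1 value per probe set), per the submitters' processing notes; the version is not given in the sources used here. Per the labels, each array carried biotinylated cRNA made from 4 µg of total RNA of the hippocampus of 1 mouse, extracted with an RNeasy Lipid kit. The scanned intensities were not used here, so background correction and normalization were not repeated. The table holds 45101 probe sets on 16 arrays, and all 16 columns were used. Labels of groups and replicates came from sample titles. The treatment label of Random antisense 1 says no treatment, against its title, source and description, which place it with the random oligonucleotide. It was kept with Random antisense and the other reading was run as an alternative.

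Removing 64 Affymetrix control probe sets left 45037, of which 34945 have 1 gene symbol in GEO's annotation of the platform, 932 have several and 9160 have none. Symbols were compared with current mouse gene names through Entrez identifiers and 0 were changed. A probe set was tested where its value was over 4 log2 on at least 4 arrays: 23905 were tested and 21132 were not. For genes and gene lists, the tested probe set of highest mean among those with 1 symbol stands for the gene, which gives 11465 genes. Other probe sets of a named gene are given where they differ in sign or most in size.

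Groups were compared in limma with a one-way layout of 4 groups of 4 arrays and contrasts between them (residual degrees of freedom 12, prior degrees of freedom 2.63), with Benjamini-Hochberg adjustment over the probe sets of each contrast and a threshold of 0.05 on the adjusted p. A moderated F test covered the 4 groups. Exact permutation p values are two-sided over the 70 ways to assign 8 arrays to 4 and 4, and their smallest value is 0.0286. The comparisons of App and array measures with an exact p were not adjusted for their number. The 4 comparisons, the filter, the gene lists, the rule for naming genes, the reversal test and most alternatives were chosen before the data were examined.

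The rule named, per comparison, up to 10 called genes of largest rise and 10 of largest fall whose 4 arrays of 1 group all lay above the 4 of the other, and up to 4 called members of each gene list, passing over clone names; where fewer than 10 genes were called, the 5 of smallest p in each direction are given as values. App was named whatever its result. Genes given as examples within a list are among those of largest change in it and were picked after their values were seen. Probe sets and genes outside the rule are marked in the text.

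The 29 gene lists, written from general knowledge, hold 894 genes, of which 726 were measured. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 29 lists of a comparison. camera compares the genes of a list with all other genes, and fry compares them with no others. The counts adjusted over the list alone use Benjamini-Hochberg within the members. Further lists for leukocyte, cell division, microglia and habenula genes were written after the arrays were seen and enter only the scores of arrays.

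Reversal was measured as the share of probe sets called between untreated SAMP8 and Control whose sign was opposite in AbPP antisense minus Random antisense, with an exact p over the labels of the 8 treated arrays. The mean move, the mean change along the direction of the line difference, was added after the share was seen, because on simulated values a full reversal gave a share of 96.5% but an exact permutation p of 0.0571, and the move gave 0.0286.

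In a self-test, 200 of 23905 simulated probe sets were given a change with the noise of each array kept. For a change of 1 log2, 62% were recovered in SAMP8 against Control with 2 wrong calls, 60.5% in AbPP antisense against Random antisense with 37, 58.5% in Random antisense against SAMP8 with 0, and 57% in AbPP antisense against SAMP8 with 42. For 2 log2 the shares were 90%, 96%, 91% and 90.5%, with 1, 49, 0 and 74 wrong calls. With no change simulated in 20 draws, the highest counts were 1, 7, 0 and 6 in the same order.

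Replicate numbers recur across groups, and whether they pair arrays was tested by the correlation of deviations from group means. Each group has 4 arrays, which limits the precision of every estimate. Sex, age and batch could not be compared: all mice are males of 12 months and the labels give no batch. Memory scores, protein levels, tissue sections and AbPP peptide levels were not analysed here. A table of mouse genes on assembly GRCm38.p6 was used only for names and the order of neighbouring genes, because the sources used here name no build for the arrays. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.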

Results

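Hippocampal RNA from 16 individual male mice aged 12 months was hybridised to 16 Affymetrix arrays, 1 mouse per array. The mice form 4 groups of 4. SAMP8 is a senescence-accelerated line that has memory deficits at 12 months. The Control line is a 50% backcross of SAMP8 with the outbred CD-1 stock, has no such deficits and was left untreated. The other groups are untreated SAMP8 mice and SAMP8 mice given an oligonucleotide intravenously, with either a random sequence (Random antisense) or a sequence directed at the amyloid beta precursor protein, AbPP (AbPP antisense). The design asks what differs between the lines, and what the AbPP antisense changes in the hippocampus of SAMP8 mice. Of 45037 probe sets, 23905 were tested, and the number of arrays per group limits the precision of each comparison. A gene is described as higher, lower or changed where its adjusted p in the limma fit lay under 0.05. Errors are SE of a difference or SD of 4 arrays. In the self-test this threshold let through more wrong calls than intended where AbPP antisense was compared. At 1 log2 there were 37 wrong beside 121 recovered against Random antisense, and 42 beside 114 against untreated SAMP8. Calls in these comparisons are therefore less certain than their adjusted p states.

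App, which encodes AbPP and is the gene the antisense is directed at, had a mean of 14.16 ± 0.19 (SD, n = 4) after AbPP antisense and 14.38 ± 0.04 after Random antisense on its brightest probe set. The AbPP antisense arrays 1 to 4 read 14.19, 14.32, 14.26 and 13.89. The Random antisense arrays read 14.43, 14.39, 14.37 and 14.34, the untreated SAMP8 arrays 14.39, 14.35, 14.35 and 14.35, and the Control arrays 14.44, 14.35, 14.46 and 13.94. The difference of -0.22 log2 (SE 0.13) had an adjusted p of 0.503 in limma, and all 4 AbPP antisense arrays lay below all 4 Random antisense arrays, which gives an exact permutation p of 0.0286 (two-sided), the smallest that 4 against 4 arrays allow. Against untreated SAMP8 the difference was -0.20 (adjusted p = 0.485, exact permutation p = 0.0286). SAMP8 minus Control was 0.07 (adjusted p = 0.999) and Random antisense minus untreated SAMP8 was 0.02 (adjusted p = 1).

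The second probe set of App read 12.81, 13.27, 13.35 and 10.59 on the AbPP antisense arrays 1 to 4. It read 13.66, 13.54, 13.52 and 13.48 after Random antisense, 13.54, 13.49, 13.50 and 13.72 in untreated SAMP8, and 13.61, 13.58, 13.59 and 13.08 in Control. AbPP antisense minus Random antisense was -1.05 (SE 0.43, adjusted p = 0.359, exact permutation p = 0.0286). The 2 other probe sets of App lay at a mean of 1.67 and 1.95 after AbPP antisense, below the filter. On AbPP antisense 4, the lowest array for both probe sets, the 3' to 5' signal difference of the control transcripts was also the largest, as described next. Without that array the second probe set differed from Random antisense by -0.41 and the brightest by -0.13. The brightest differed by -0.12 with the beta-actin 3' to 5' difference as a covariate, a fit chosen after the data were seen.

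**Figure D1:**
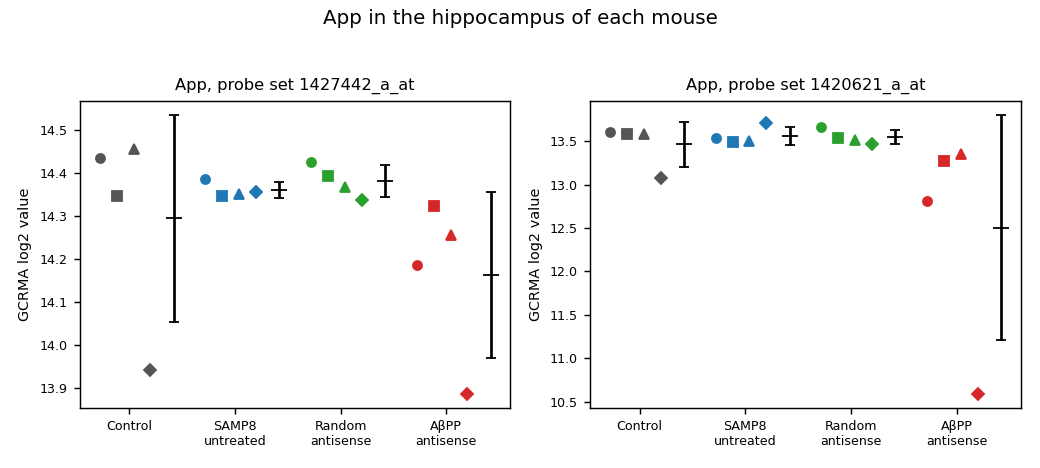
Level of App in each mouse on the GCRMA log2 axis, for the 2 probe sets that passed the filter. Each point is a mouse (circle, square, triangle and diamond for replicates 1 to 4) and the black bar is the group mean ± SD (n = 4). The 4 AbPP antisense points lie below the 4 Random antisense points in both panels, with AbPP antisense 4 lowest at 13.89 and 10.59.

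Several array measures set single arrays apart. The 3' minus 5' difference of the Gapdh control probe sets, which rises as RNA is degraded, was 0.21 ± 0.72 after AbPP antisense and -0.34 ± 0.04 after Random antisense (exact permutation p = 0.0857). For beta-actin it was 2.08 ± 1.23 and 1.27 ± 0.06 (exact permutation p = 0.143). AbPP antisense 4 had 1.26 for Gapdh and 3.89 for beta-actin, AbPP antisense 1 and 2 had 1.60 for beta-actin, and AbPP antisense 3 had -0.35 and 1.21. The median correlation with the other 15 arrays was 0.905 for AbPP antisense 4 and 0.922 for Control 4, against 0.982 over all 120 pairs. A score, the median deviation of a marker list from its mean on the 14 arrays other than Control 4 and AbPP antisense 4, was 4.78 on Control 4 for genes shared by all leukocytes. The choroid plexus score was -0.70, -1.53, -1.16 and -0.09 on the AbPP antisense arrays 1 to 4. The thalamus score was -1.46, -0.10, -1.34 and 0.36, and the blood score 0.14, 3.94, -0.17 and 1.70.

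**Figure D2:**
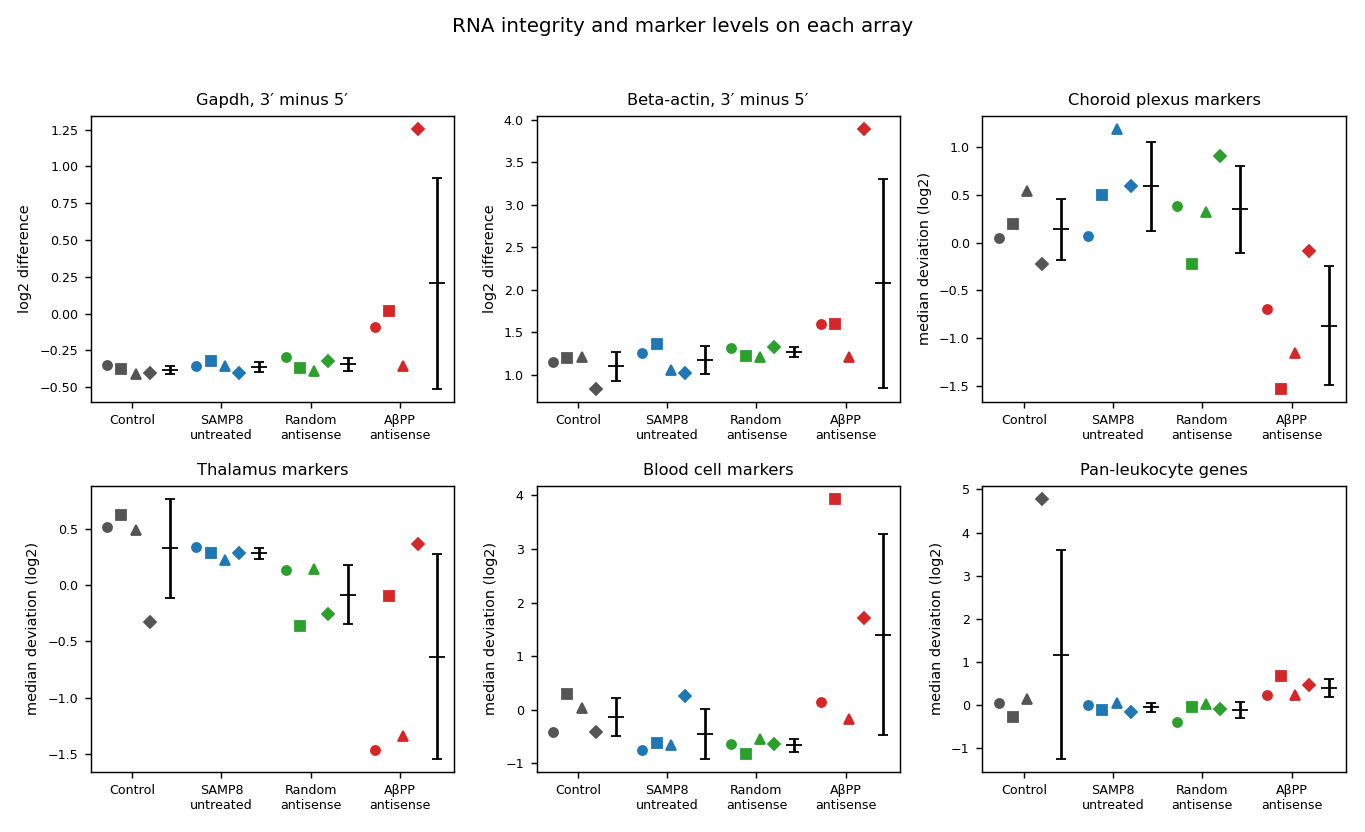
RNA integrity (3' minus 5' log2 difference of Gapdh and beta-actin) and marker scores (median log2 deviation of a list) on each array, by group. Points are mice, with shapes for replicates 1 to 4, and black bars are group means ± SD (n = 4). AbPP antisense 4 stands highest in both integrity panels (1.26 and 3.89), and Control 4 alone in the leukocyte panel (4.78).

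The genes that differed between untreated SAMP8 and Control mice, with and without memory deficits, included those of enzymes, signalling proteins and a heat shock protein. Galc, the lysosomal galactosylceramidase that degrades myelin lipids, was 4.65 log2 higher in SAMP8 on its brightest probe set (SE 0.67, adjusted p = 0.00328). It lay at 8.57 ± 0.11 (SD, n = 4) against 3.92 ± 2.05, with Control arrays from 2.28 to 6.59. The Control mean lies under the filter level of 4, so the size of the difference is uncertain. A second probe set of Galc was called in the opposite direction (-1.93), so the direction for the gene is uncertain too. Nudt19, a nudix hydrolase, was 1.52 higher (SE 0.20, adjusted p = 0.00202), and Hspa1a, an inducible heat shock protein, was 1.53 higher (SE 0.29, adjusted p = 0.0329), at 6.66 ± 0.56 against 5.14 ± 0.36. Cap1, an actin-binding protein, fell by 3.24 in SAMP8 (SE 0.38, adjusted p = 0.000542), from 11.12 ± 0.85 to 7.88 ± 0.21. Gnb1, a G protein beta subunit, fell by 2.35 (SE 0.28, adjusted p = 0.000681), from 13.11 ± 0.20 to 10.76 ± 0.32, and its 2 other probe sets fell too (-3.00 and -2.29). Akr1e1, an aldo-keto reductase, fell by 1.70 (SE 0.13, adjusted p = 8.04e-06), from 7.26 ± 0.22 to 5.57 ± 0.03. Gstp1, a glutathione transferase of the antioxidant list, fell by 0.70 (SE 0.13, adjusted p = 0.0272).

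The other genes named by the fixed rule were higher in SAMP8 for Efhd2 (1.87, adjusted p = 0.00328), Vmn2r29 (1.82, 0.0161), Vamp3 (1.67, 0.0046), Tnfaip2 (1.65, 0.00328), Dus4l (1.08, 0.0331), Cep89 (1.07, 0.00915) and Prex2 (1.07, 0.0145). Lower were Zfp551 (-3.74, adjusted p = 5.71e-06), Tekt5 (-2.71, 0.000542), Noc2l (-1.38, 0.00295), Inpp4a (-1.36, 0.00328), Exosc9 (-0.90, 0.00127), Nit2 (-0.84, 0.0473) and Zcchc9 (-0.82, 0.0458). Zfp551 and Tekt5 had SAMP8 means under the filter level (2.43 and 2.92), so the sizes of their differences are uncertain. They include a vomeronasal receptor (Vmn2r29), a vesicle SNARE (Vamp3), an exchange factor for Rac (Prex2) and a subunit of the RNA exosome (Exosc9). Other probe sets of these genes often differed from the named one. A second probe set fell by 1.93 for Galc and rose by 2.14 for Noc2l, both past the threshold and opposite to the named one, while those of Efhd2 (0.25), Inpp4a (0.11) and Dus4l (-0.05) and the 4 of Vamp3 (-0.15 to 0.09) did not pass. Cap1 had a second probe set at -3.52, past the threshold and in the same direction.

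In all, 86 probe sets differed between the lines, 43 higher and 43 lower in SAMP8, and 1047 had an unadjusted p under 0.05 where 1195 would by chance. They cover 54 genes, 26 of them by the brightest probe set (14 higher, 12 lower). Leaving out SAMP8 replicate 2, 3 or 4 gave 57, 54 and 56 probe sets. With 1 array left out in turn, 14 of the 21 genes kept their call in all 16 fits. Vmn2r29 lost it without Control 4 or SAMP8 3 or 4 (highest adjusted p = 0.077), Prex2 without SAMP8 2 or 3 (0.0708), and Gstp1 without Control 1, 2 or 3 or SAMP8 2, 3 or 4 (0.124). Hspa1a lost it without Control 1, 2 or 4, SAMP8 1, 2 or 3, or Random antisense 1, 2 or 4 (0.155), and Dus4l without any of these arrays, Random antisense 3 or AbPP antisense 2 (0.149). Nit2 kept it only without Control 2, Random antisense 1 or AbPP antisense 4 (highest adjusted p otherwise 0.216), and Zcchc9 only without Control 1 or AbPP antisense 4 (0.171). In a fit of only the 8 arrays compared 37 probe sets were called, and 14 of the 21 genes lost their call, among them Galc (adjusted p = 0.165), Nudt19 (0.084), Hspa1a (0.183), Efhd2 (0.084) and Gstp1 (0.156).

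**Figure D3:**
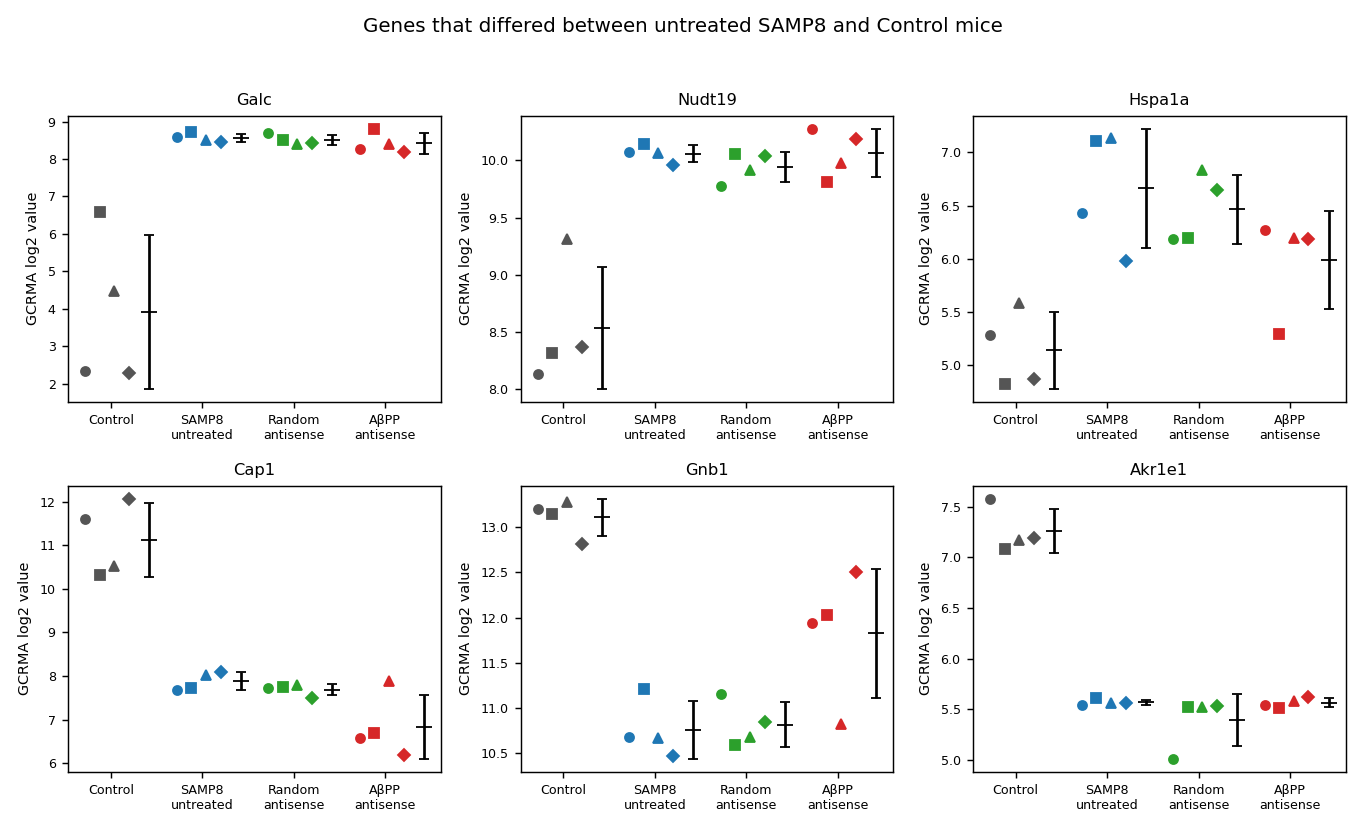
GCRMA log2 level of 6 genes that differed between untreated SAMP8 and Control mice, in all 4 groups. Points are mice, with shapes for replicates 1 to 4, and black bars are group means ± SD (n = 4). On the probe sets shown, Galc, Nudt19 and Hspa1a are higher in SAMP8 and Cap1, Gnb1 and Akr1e1 lower. After AbPP antisense, Gnb1 (11.83) lies above and Cap1 (6.84) below the SAMP8 mean (10.76 and 7.88).

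Among 29 gene lists fixed in advance, 9 differed between untreated SAMP8 and Control by camera with a preset correlation, and 0 with an estimated correlation or by fry, which asks whether the genes of a list move on balance in 1 direction. Activity-induced immediate-early genes had a median of 0.31 in SAMP8, with 28 of 35 positive (adjusted p = 0.0225, and adjusted p = 0.725 with an estimated correlation). Npas4 (1.61), Arc (1.42) and Fos (1.13), transcription and synaptic genes induced by neuronal firing, led the list, all with adjusted p = 0.999. Cholesterol synthesis genes had a median of 0.18, with 20 of 22 positive (adjusted p = 0.00268, 0.694 as the adjusted p with an estimated correlation), led by Dhcr7 (0.45, adjusted p = 0.999). Without Control 4 and AbPP antisense 4 both lists kept their call (adjusted p = 0.000655 and 0.000869). The thalamus list, at a median of -0.27, was called only then (adjusted p = 0.00574 against 0.388 with all arrays).

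The 7 other lists lost their call without these arrays, and each had adjusted p = 0.694 with an estimated correlation. Interferon-stimulated genes had a median of -0.75 in SAMP8, with 25 of 27 negative (adjusted p = 1.93e-07), and 0.05 without the arrays (adjusted p = 0.209). The interferon score was 3.25 on Control 4. Microglia markers had -0.44 with 21 of 26 negative (adjusted p = 7.92e-05), and 0.15 without the arrays (adjusted p = 0.45), with a score of 1.55 on Control 4. Cytokine genes had -0.30 with 12 of 15 negative (adjusted p = 0.00268, then 0.813). Glutamatergic synapse genes had 0.19 with 31 of 33 positive (adjusted p = 0.00501, then 0.785), and presynaptic vesicle genes 0.15 with 30 of 33 positive (adjusted p = 0.00268, then 0.785). Striatum markers had 0.40 with 15 of 15 positive (adjusted p = 0.00268, then 0.0612), and choroid plexus markers 0.41 with 14 of 16 positive (adjusted p = 0.00626, then 0.0612). Over all genes tested, the members past the threshold were Gstp1 of the antioxidant list and Hspa1a of the heat shock list. Adjusted over the list alone, the antioxidant list had 1 lower and the heat shock list 1 higher and 1 lower, and the other 27 lists had 0 by limma. The blood cell list, not called (adjusted p = 0.107), had a median of 0.04 but a mean of -1.01, and the test pointed down. The insulin (0.04, -0.01) and dentate gyrus (0.05, 0.06) lists, also not called, had a median and mean that differed in sign from each other or from the test, which pointed down.

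The comparison of the oligonucleotide sequence, AbPP antisense against Random antisense, called 3 genes by their brightest probe set. Dync1li1, a light intermediate chain of the dynein motor, fell by 3.08 log2 (SE 0.23, adjusted p = 2.93e-05), to 6.68 ± 0.61 (SD, n = 4) from 9.76 ± 0.18. Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, fell by 1.13 (SE 0.19, adjusted p = 0.0394) from 6.13 ± 0.09. Slc2a5, a fructose transporter found in microglia, rose by 1.01 (SE 0.15, adjusted p = 0.0181), to 4.91 ± 0.33 from 3.90 ± 0.17, which lies under the filter level, so the size is uncertain. The genes next in p did not pass: Prom1 (0.77, adjusted p = 0.0688), Nrarp (0.98, 0.0801, other probe set 0.19), Vcam1 (0.56, 0.0801), Ramp2 (0.98, 0.0913), Clic6 (-1.88, 0.0688), Ankrd45 (-1.61, 0.0688) and Xrn1 (-1.63, 0.0801). With 1 array left out in turn, Dync1li1 kept its call in all 16 fits. Slc2a5 lost it without Random antisense 1, 2 or 3 (highest adjusted p = 0.107), and Irak2 without Control 1, 2 or 3, any untreated SAMP8 or Random antisense array, or AbPP antisense 1 (0.152). In a fit of only the 8 arrays compared, none of the 3 passed, with adjusted p = 0.0602 for Dync1li1, 0.359 for Slc2a5 and 0.464 for Irak2.

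In all, 20 probe sets differed after AbPP antisense, 3 higher and 17 lower, and 2935 had an unadjusted p under 0.05 where 1195 would by chance. Those outside the naming rule, picked out after their values were seen, include 2 probe sets of Nudt21, an mRNA 3' processing factor (-4.02 and -3.46, with a further probe set at 0.02), Ube2b, a ubiquitin-conjugating enzyme (-3.18, with 3 others from -0.40 to 0.04), and Kcna6, a potassium channel (-2.14, with 2 others from -0.84 to 0.14). Kcna6 read under the filter level on all 4 AbPP antisense arrays (2.01 to 3.02) and Lasp1 on 3 of them (3.34 to 3.79), so the sizes of their differences are uncertain. Single probe sets were also lower of Rcan2 (-1.73, other -0.42), Plekhh1 (-1.70, others -1.68 and -0.15) and Acbd3 (-1.52, 3 others from -1.15 to -0.33). The same held for Lasp1 (-1.46, 6 others from -0.17 to 0.16), Mzt1 (-1.38, others -0.22 and -0.11) and Trappc13 (-0.93, others 0.08 and 0.17), and 6 called probe sets have no single gene symbol. The count moved with the arrays entering the fit: it was 11 without Random antisense 1, 2 or 3, 58 without Control 4, and 31, 35, 896 and 68 without AbPP antisense 1, 2, 3 and 4 in turn. Without both Control 4 and AbPP antisense 4 it was 199, which include all 20, and in a fit of only the 8 arrays compared it was 0.

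Choroid plexus markers fell as a group after AbPP antisense: 16 of 16 were negative against Random antisense, with a median of -1.57 (camera adjusted p = 1.04e-16, adjusted p = 0.0466 with an estimated correlation, fry adjusted p = 0.0137). Kcne2, a potassium channel subunit, had -2.75 (SE 0.62), Kcnj13, a potassium channel, -2.59 (SE 0.56), Folr1, the folate receptor, -2.53 (SE 0.51), Ttr, the thyroxine carrier transthyretin, -2.34 (SE 0.60) and Kl, klotho, -2.27 (SE 0.50). Over all genes tested 0 of the 16 passed in limma (adjusted p from 0.0688 for Clic6), and 12 were lower when adjusted over the list alone. Without Control 4 and AbPP antisense 4 the median was -1.91, and 6 were lower over all genes. Choroid plexus lies beside the hippocampus, and the choroid score of the AbPP antisense arrays (-0.70, -1.53, -1.16 and -0.09) against those of Random antisense (0.38, -0.22, 0.32 and 0.90) gave an exact permutation p of 0.0571. The microglia, endothelial and mural, cytokine, blood cell, cholesterol and leukocyte scores each gave an exact permutation p of 0.0286, and all other scores gave larger values. These values were not adjusted for the number of lists. Endothelial and mural markers rose (median 0.26, 16 of 20 positive, adjusted p = 0.000139, fry adjusted p = 0.0203), with an adjusted p of 0.174 with an estimated correlation. Adjusted over the list alone 6 were higher, among them Higd1b (1.40), Slco1a4 (0.83) and Rgs5 (0.54), and 0 over all genes by limma.

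The 12 other lists called by camera had no member past the threshold over all genes or adjusted over the list alone, and lost their call with an estimated correlation. Without Control 4 and AbPP antisense 4, 3 thalamus markers were lower over all genes, and 2 microglia, 1 blood cell and 1 oligodendrocyte marker were higher. Activity-induced immediate-early genes had a median of -0.34 with 28 of 35 negative (adjusted p = 0.000242, and adjusted p = 0.565 with an estimated correlation), led by Fos (-1.49, adjusted p = 0.386). AbPP antisense 2 had the lowest score of that list (-1.03). Heat shock and unfolded protein response genes had -0.12 with 28 of 37 negative (adjusted p = 0.000875, and 0.187 with an estimated correlation). Microglia markers had 0.41 with 23 of 26 positive (adjusted p = 0.00198), and oxidative phosphorylation genes 0.12 with 51 of 71 positive (adjusted p = 0.00339). Thalamus markers had -0.43 with 16 of 18 negative (adjusted p = 0.00207), oligodendrocyte markers -0.18 with 19 of 25 negative (0.0105), meninges markers -0.30 (0.0136), presynaptic vesicle genes -0.11 (0.0148), CA2 and CA3 markers -0.15 (0.0136), ependyma markers -0.22 (0.0477) and cholesterol synthesis genes 0.17 (0.0289). Each of these 9 had adjusted p = 0.565 with an estimated correlation. Blood cell markers had 1.94 with 6 of 7 positive (adjusted p = 0.00849, 0.457 as the adjusted p with an estimated correlation), and the blood score was highest on AbPP antisense 2 (3.94).

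Of the lists nearest the antisense target, APP and its processing had adjusted p = 0.167, neurotrophin and MAPK signalling 0.102, and insulin and PI3K-AKT-mTOR signalling 0.339. With the mean of all probe sets of a gene in place of the brightest, neurotrophin and MAPK signalling was called, pointing down (adjusted p = 0.00043), and so was the GABAergic list (0.03), while the meninges (0.0736), CA2 and CA3 (0.121), ependyma (0.178) and cholesterol (0.256) lists lost their call. The others not called were antioxidant defence (0.0731, fry adjusted p = 0.0203), cytokine (0.0648), glucocorticoid-induced (0.117), circadian clock (0.167), GABAergic (0.167), interferon-stimulated (0.34), glutamatergic (0.369), astrocyte (0.376), striatum (0.376), CA1 (0.687), dentate gyrus (0.832) and Wnt (0.883). Median, mean and test differed in sign for Wnt (0.07, 0.01, down), glutamatergic (0.00, -0.04, down) and dentate gyrus (0.02, -0.10, down). Adjusted over the list alone, Mt2, a metallothionein in both the antioxidant and the glucocorticoid list (0.79), and the brightest probe set of Vcam1, an adhesion molecule of the cytokine list (0.56, with 2 others at -0.40 and 0.01), were higher. Without Control 4 and AbPP antisense 4 the cholesterol (adjusted p = 0.07), ependyma (0.0619) and CA2 and CA3 (0.0745) lists lost their call, and the interferon (0.00658) and astrocyte (0.00375) lists gained one.

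Random antisense against untreated SAMP8, the comparison of an oligonucleotide with no treatment, called 0 of 23905 probe sets in limma, where the smallest adjusted p was 0.922. At an unadjusted p under 0.05 there were 267, where 1195 would by chance, and fits of a single variance per probe set without moderation also called 0 after adjustment. Residual spread relative to the average was 0.37 to 0.51 on these arrays, 1.24 to 1.99 after AbPP antisense and 1.84 on Control 4. The shared variance is thus likely too large for this comparison and its p values too high, so 0 calls do not show a lack of effect. With array weights, limma called 19. The genes of smallest p, given as values, were Etv5 (0.48), Cxcl13 (1.59, other probe set 3.35), Med13l (0.34), Smg9 (0.42), Satb1 (0.40), Rxrg (-1.07), Nt5e (-0.45), Erlin2 (-0.35), Gadd45g (-0.58) and Jmjd6 (-0.32, other -0.12), all with adjusted p = 1. In a limma fit of only the 8 arrays compared, their adjusted p lay between 0.229 (Etv5) and 0.292 (Rxrg). Oxidative phosphorylation genes, subunits of the respiratory chain, had a median of -0.11 with 65 of 71 negative (camera adjusted p = 3.92e-12, adjusted p = 0.403 with an estimated correlation). Thalamus markers had -0.49 with 17 of 18 negative (0.000157, estimated correlation adjusted p = 0.835), striatum markers -0.38 (6.4e-05, estimated 0.509) and ependyma markers -0.33 (0.00103, estimated 0.475). SAMP8 3 had the highest striatum and ependyma scores of its group (1.08 and 0.53). The other untreated SAMP8 arrays had -0.13 to 0.09 and -0.11 to 0.13. Cholesterol synthesis genes had -0.14 (0.00103, estimated 0.35), antioxidant genes -0.07 (0.0296, estimated 0.287) and oligodendrocyte markers -0.11 (0.0452, estimated 0.984). Glutamatergic genes had 0.08 (0.00285, estimated 0.872), presynaptic genes 0.04 (0.0339, estimated 0.984) and insulin signalling genes 0.04 (0.0474, estimated 0.287). None of these 10 lists was called by fry or held a member past the threshold, over all genes or adjusted over the list alone. Without Control 4 and AbPP antisense 4 the oligodendrocyte (adjusted p = 0.0854) and insulin (0.0723) lists lost their call, and with the mean of all probe sets of a gene the insulin list did (0.0705).

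AbPP antisense against untreated SAMP8 called 11 genes. Slc2a5 rose by 0.94 (SE 0.15, adjusted p = 0.0252), from a mean of 3.97 under the filter level, so the size is uncertain. Mertk, a receptor for the uptake of dying cells, rose by 0.79 (SE 0.14, adjusted p = 0.0295), to 9.15 ± 0.14 (SD, n = 4) from 8.35 ± 0.23. Dync1li1 fell by 3.05 (SE 0.23, adjusted p = 3.38e-05), Irak2 by 1.16 (SE 0.19, adjusted p = 0.0221), Xrn1, an exoribonuclease of mRNA decay, by 1.87 (SE 0.33, adjusted p = 0.0295) and Ankrd45 by 1.73 (SE 0.31, adjusted p = 0.0295). Of the choroid plexus list, Kcnj13 fell by 3.38 (SE 0.56, adjusted p = 0.0279), Folr1 by 2.90 (SE 0.51, adjusted p = 0.0295), Kl fell by 2.61 (SE 0.50, adjusted p = 0.0427) and Clic6, a chloride channel, fell by 2.45 (SE 0.35, adjusted p = 0.00837). Calml4 fell by 2.66 (SE 0.44, adjusted p = 0.0279). In every leave-one-out fit Dync1li1 and Clic6 kept their call. In a fit of only the 8 arrays compared, Dync1li1 kept its call (adjusted p = 0.0364) and the other 10 lost it (Clic6 0.165, Slc2a5 0.353, and Kcnj13, Folr1 and Kl 0.373 each).

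The 9 other genes lost their call in 5 to 12 of the 16 fits. Slc2a5 (highest adjusted p = 0.124) and Irak2 (0.122) lost it without any untreated SAMP8 array or AbPP antisense 1. Without any SAMP8 array, Random antisense 1 or 3, or AbPP antisense 1, Kcnj13 (0.126) and Calml4 (0.131) lost it, and with Random antisense 2 added so did Mertk (0.131) and Folr1 (0.133). Xrn1 (0.131) lost it without any SAMP8 array, Random antisense 1, 2 or 3, or AbPP antisense 2, and Ankrd45 (0.134) without SAMP8 1, 3 or 4, Random antisense 1, 2 or 3, or AbPP antisense 1. Kl (0.17) lost it without Control 1, 2 or 3, any SAMP8 or Random antisense array, or AbPP antisense 4.

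In this comparison 69 probe sets differed, 9 higher and 60 lower, and 3507 had an unadjusted p under 0.05. Of the 20 called against Random antisense, 19 were called here in the same direction. The comparisons share the AbPP antisense arrays, so this is not independent evidence: independent lists would share 0.0427 lower and 0.00113 higher probe sets, and simulated arrays with no change shared 0 to 6 in 20 draws. With the AbPP antisense arrays parted 2 and 2 between the comparisons in 6 ways, 46 to 3995 probe sets were called against Random antisense and 67 to 4796 against untreated SAMP8, of which 20 to 82 were called in both; this overlap was not compared with values of no change. The count was 17, 23, 16 and 17 without untreated SAMP8 1, 2, 3 and 4, 24, 26 and 21 without Random antisense 1, 2 and 3, and 137 without Control 4. It was 36, 105 and 1286 without AbPP antisense 1, 2 and 3, and 401 without both Control 4 and AbPP antisense 4. In a fit of only the 8 arrays compared it was 5.

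Choroid plexus markers again had 16 of 16 negative, with a median of -1.74 (camera adjusted p = 3.06e-18, adjusted p = 0.0336 with an estimated correlation, fry adjusted p = 0.00283), 4 lower over all genes and 13 adjusted over the list alone. Thalamus markers had -0.96 with 17 of 18 negative (1.45e-07, estimated correlation adjusted p = 0.554), and Zic1 (-1.84) and Prkcd (-1.81) were lower when adjusted over the list alone. Ependyma markers had -0.50 (0.000155, estimated correlation adjusted p = 0.413), with 4 lower adjusted over the list alone, among them Dynlrb2 (-1.59) and Tmem212 (-1.29). Endothelial and mural markers had 0.34 with 18 of 20 positive (0.000138, estimated 0.21, fry adjusted p = 0.0333). Immediate-early genes had -0.34 with 31 of 35 negative (1.49e-05, estimated 0.554), led by Fos (-1.80, adjusted p = 0.237). Microglia markers had 0.40 (0.000667, estimated 0.71), oligodendrocyte markers -0.26 (0.000155, estimated 0.71) with Tspan2 (-1.05) lower over the list alone, and heat shock genes -0.11 (0.00284, estimated 0.35) with 2 lower over the list alone, among them Pdia3 (-0.93). CA2 and CA3 markers had -0.26 (0.00289, estimated 0.554), meninges markers -0.38 (0.0256, estimated 0.71) and blood cell markers 1.28 (0.0372, estimated 0.554). Of the lists not called, interferon-stimulated genes had 1 higher when adjusted over the list alone. The thalamus score was lowest on AbPP antisense 1 and 3 (-1.46 and -1.34). With the mean of all probe sets of a gene, the neurotrophin (adjusted p = 0.00677) and GABAergic (0.0315) lists were called, pointing down, and the meninges list lost its call (0.121). In no called list of any comparison did median, mean and test differ in sign.

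**Figure D4:**
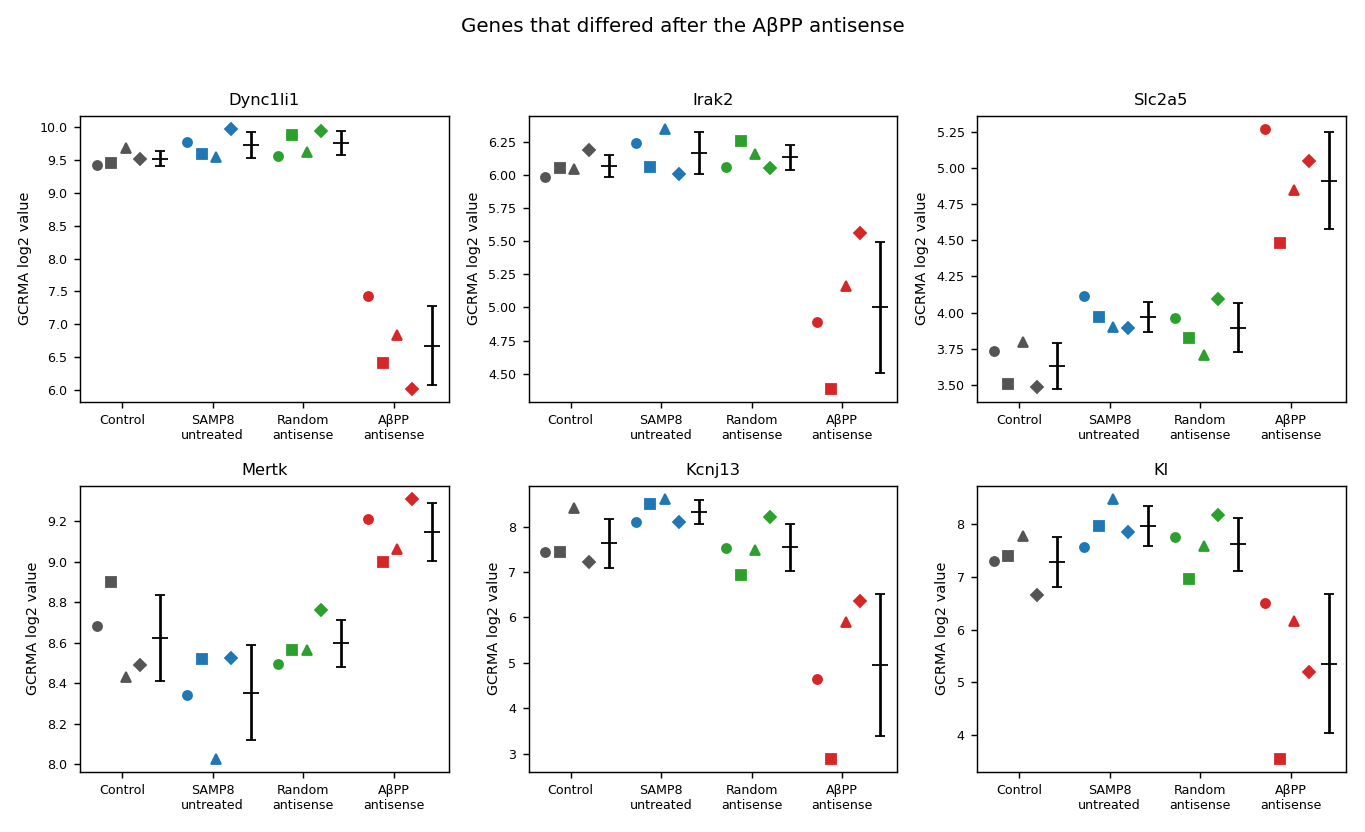
GCRMA log2 level of 6 genes that differed after AbPP antisense from untreated SAMP8, in all 4 groups. Points are mice, with shapes for replicates 1 to 4, and black bars are group means ± SD (n = 4). Dync1li1 (6.68 against 9.76 after Random antisense) and Irak2 (-1.13) are lower on all 4 AbPP antisense arrays, and Slc2a5 (4.91 against 3.90) is higher.

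Whether the AbPP antisense moved the genes of the line difference back towards Control was tested over the 86 probe sets that differed between the lines. For these, sequence variants under the probes could not be told apart from expression. In SAMP8 mice that share a genotype, a difference due to such a variant could not move back, so a lack of movement says little about expression. Of these, 36 (41.9%) had the opposite sign in AbPP antisense minus Random antisense and 50 the same sign, with an exact permutation p of 0.371 over the 70 ways to label the 8 treated arrays. Without AbPP antisense 2 or 3 the share was 59.3% and 53.0%, on the other side of even. Pearson's r of the changes was 0.07 across these probe sets, which are not independent replicates. On a scale from 0 at the untreated SAMP8 mean to -1 at the Control mean, the median position of the treated arrays lay between -0.03 and 0.03. The mean move along the line difference was 0.02 log2 against a mean size of 1.91 for that difference (exact permutation p = 0.571). Only 2900052N01Rik, singled out after its values were seen, was called in both comparisons, where independent lists would share 0.072; it was lower in SAMP8 than in Control and 1.01 higher after AbPP antisense (adjusted p = 0.00776). Gnb1 and Cap1, both lower in SAMP8, read 11.94, 12.03, 10.83 and 12.50 and 6.57, 6.69, 7.89 and 6.19 on the AbPP antisense arrays.

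Against Control, 775 probe sets differed after AbPP antisense (319 higher, 456 lower) and 100 after Random antisense (51 higher, 49 lower); the difference between these counts was not tested. With array weights the counts were 276 and 719, in the opposite order. Both counts depended on single arrays too. The first was 309 and 421 without Control 1 and 2, 430, 473, 469 and 472 without untreated SAMP8 1 to 4, 466, 438 and 425 without Random antisense 1, 2 and 3, and 2616 without AbPP antisense 3. The second was 62, 62 and 63 without Random antisense 2, 3 and 4. Across the 4 groups, the moderated F test of limma called 203 probe sets, with 3354 at an unadjusted p under 0.05. That count was 126, 124 and 122 without untreated SAMP8 1, 3 and 4, 120, 135 and 117 without Random antisense 1, 2 and 3, and 963 without AbPP antisense 3.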

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

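The tests of white blood cells and of microglia alone, the tests of RNA quality, dissection and whole transcript for the AbPP antisense group, and the comparison of the probe set ratios of 2 comparisons were chosen only after the result was seen; the others were written before.

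Control 4 stood apart from the other arrays (median r 0.922), with a leukocyte score of 4.783, a cell division score of 3.467 and an interferon score of 3.251. RNA quality does not account for it: its 3' to 5' difference lay 0.183 log2 outside the range of 14 arrays, against 2.29 on AbPP antisense 4. Nor do choroid plexus, ependyma, meninges, thalamus or striatum, where the highest list score was -0.117 for meninges. The blood list, at -0.424 on Control 4, cannot decide on blood. Its members Ighm, S100a8 and S100a9 read 11.34, 12.87 and 11.91 there, but Alas2, Bpgm, Hbb-b2 and Slc4a1 read 4.23, 9.77, 5.76 and 3.61. Tissue without a list was not tested. Activated microglia alone are not the likely source, because microglia genes low in blood leukocytes, minus the leukocyte genes, gave -5.064. White blood cells or their precursors may be, with Ptprc at 12.5 against 5.07 to 6.90 on the other arrays, but the rule asked for under 0.5 elsewhere and AbPP antisense 2 had 0.666, so this test does not decide. Interferon, cytokine and microglia lists lost their call in SAMP8 minus Control without this array and AbPP antisense 4, so these calls may rest on Control 4 rather than on the line.

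The AbPP antisense arrays differed from Random antisense in 20 probe sets, and in 896 without AbPP antisense 3, whose 3' to 5' differences resemble the other groups. With the beta-actin difference as a covariate, the 20 kept a median of 0.950 of their change (interval 0.921 to 1.07) at 1.04 times the SE, and 17 were among the 59 then called. This cannot decide on RNA quality as their cause. The covariate is set mainly by AbPP antisense 4 (3.89, against 0.84 to 1.60 on the other arrays), and the 20 were called with all 4 AbPP antisense arrays in the fit. The covariate fit shows only that their change did not rest on AbPP antisense 4 alone. On AbPP antisense 3, where the 3' to 5' differences resemble the other groups, all 20 lay beyond all 4 Random antisense arrays in the called direction. That array helped to select them, so this does not decide either. For the 896 RNA quality cannot be told apart from other causes. AbPP antisense 3 showed a median of 0.0534 of their change (interval 0.0398 to 0.0726), as any cause that sets this array apart would give. Probe sets called from AbPP antisense 1 and 2 alone changed 1.71 times as much on AbPP antisense 4 (interval 1.56 to 1.84). The rule for degradation in proportion asked for over 2, and a value of 1 or less would have argued against it. That cut-off is loose: beta-actin was 3.89 on AbPP antisense 4, 1.60 on 1 and 2, and 1.27 on average after Random antisense. Strict proportion to these differences would ask for more than 2. The ratio falls short of that, but it rests on 1 array and does not decide. A smaller share of choroid plexus and thalamus in the dissected tissue cannot be told apart from a treatment effect, with a median ratio of 0.566 on AbPP antisense 4 (interval 0.387 to 0.907). Nor can a change of the whole transcript be told apart from one of single probe sets, since other probe sets of 10 called genes moved by a median of 0.141 of the called change (interval 0.0234 to 0.296); these intervals were added after the values were seen.

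The 86 probe sets called between the lines could reflect expression, sequence variants under the probes or linked blocks of the genome that differ between SAMP8 and the CD-1 backcross. Sequence variants cannot be told apart from expression here. In 40 called genes with other probe sets, those moved by a median of 0.0254 of the called change (interval -0.0155 to 0.133). The same ratio was 0.141 (interval 0.0234 to 0.296) in AbPP antisense minus Random antisense. Both of those groups are labelled SAMP8, so variants between the lines should not act there. Whether the mice of those groups shared a genotype was not tested. Linked blocks fit: 4 called genes lay next to another called gene, as Mul1 with Camk2n1 and Cep89 with Nudt19, where the 95th percentile of 10000 random draws was 2. These explanations do not exclude each other, and an effect of the line on expression stays open.

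On AbPP antisense 4 the 3' to 5' difference lay 2.292 outside the range of 14 arrays, so RNA quality fits. Its highest score of tissue from outside the hippocampus was 1.703, for blood cells, which fits by the rule written before, although AbPP antisense 2 has a higher blood score (3.94) with a median r of 0.958 against 0.905.

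Of the 35 ways to split the 8 arrays of a comparison, only 1, the real one, gave as many calls for SAMP8 minus Control (86, highest other 3), for AbPP antisense minus Random antisense (20, highest other 1) and for AbPP antisense minus untreated SAMP8 (69, highest other 0). The real split is always among the 35, so 1 is the lowest result possible. Chance assignment of arrays is thus unlikely for these but not excluded. Random antisense minus untreated SAMP8 had 0 calls to test, so 35 of 35 splits give as many by construction (highest other 0). For the F test 1 of 100 splits gave as many (203, highest other 79), again the lowest result possible, so chance is unlikely but not excluded.

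Single arrays were compared with the 3 others of their group by Dixon's ratio in 332 groups of values, where chance picks out about 1 in 20 groups, or 16.6, and 28 were picked out: 14 on Control 4, 1 on AbPP antisense 4 and 13 on other arrays. On Control 4 the scores were -0.787 for glutamatergic, -0.738 for presynaptic, -0.720 for GABAergic and -0.162 for insulin signalling genes, and 1.05 for cytokine genes. Its scores for brain regions were -0.327 for thalamus, -0.686 for striatum, -0.735 for dentate gyrus, -0.698 for CA1 and -0.835 for habenula. The second probe set of App read 13.08 on Control 4.

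On other arrays, Control 1 had an antioxidant score of 0.114. SAMP8 4 had Tekt5 at 3.34, Gadd45g at 7.66 and a blood score of 0.25, SAMP8 3 had Prom1 at 7.87, and SAMP8 2 a microglia score of -0.171. Random antisense 1 had Akr1e1 at 5.007, Random antisense 3 had Tekt5 at 2.69, and Random antisense 4 had Xrn1 at 7.93, a neurotrophin score of -0.0304 and a CA1 score of -0.347. AbPP antisense 2 had Hspa1a at 5.29 and an immediate-early score of -1.03, and AbPP antisense 4 a beta-actin 3' to 5' difference of 3.89. The 18S ribosomal RNA control probe set, not used in the comparisons, read 10.23 on SAMP8 2, 11.04 on AbPP antisense 1 and 14.72 on AbPP antisense 4, above the highest Control array (9.33).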

How the results depend on the processing

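No test in this part was chosen after the result was seen apart from the alternatives named as added and the mean move, and the cause of a moved count was not tested. Counts below are called probe sets of SAMP8 minus Control (86 as reported), AbPP antisense minus Random antisense (20), Random antisense minus untreated SAMP8 (0), AbPP antisense minus untreated SAMP8 (69), AbPP antisense minus Control (775), Random antisense minus Control (100) and the F test (203). None of the 35 calls of named genes changed sign in any setting. A gene called in more than 1 comparison counts once in each (21, 3 and 11 calls). The fewest calls were kept with only the 8 samples compared (8) and without SAMP8 replicate 3 (18), and 24 were kept without the filter. Centring the arrays and an intensity trend with a robust prior moved no count past the tolerance of 1.5.

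Without the filter, AbPP antisense minus untreated SAMP8 gave 31, AbPP antisense minus Control 456, and the mean move of the line genes was -0.0294. With a filter at 6 log2, AbPP antisense minus Random antisense gave 13. After quantile normalization again, the share reversed was 51.1% and the move -0.0642. With 1 probe set per gene, SAMP8 minus Control gave 24, AbPP antisense minus Random antisense 2, AbPP antisense minus untreated SAMP8 10, and AbPP antisense minus Control 84. Random antisense minus Control then gave 27, the F test 37, and the move was -1.67e-05.

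With array weights, SAMP8 minus Control gave 295, AbPP antisense minus Random antisense 35, of which 14 were among the 20, and Random antisense minus untreated SAMP8 19. AbPP antisense minus Control then gave 276, Random antisense minus Control 719 and the F test 564. The move was -0.000941, and App in SAMP8 minus Control was -0.0487.

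A one-way fit without moderation at an unadjusted p under 0.05 gave 1045, 2836, 384, 3421, 5515, 2040 and 3212 in the order above, with a share of 51.2% and a move of -0.0138. After adjustment it gave 31 for AbPP antisense minus untreated SAMP8, 496 for AbPP antisense minus Control and 133 for the F test, with a move of -0.0353. An unadjusted p under 0.05 with at least a 1.5-fold change gave 556, 1513, 63, 1982, 3192 and 928, and, as an added alternative, a share of 51.98% and a move of -0.0536. With the line genes taken at an unadjusted p under 0.01, the share was 50.6% and the move -0.0184.

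With replicate number as a block, AbPP antisense minus Control gave 460 and the move was -0.0353. In the pairing check, r of deviations ran from -0.275 to 0.236. Of the 8 arrays of each of the first 4 comparisons, 5, 4, 5 and 2 correlated best with the array of their own number. Pairing by replicate number is therefore not excluded. Counting Random antisense 1 as untreated SAMP8 gave 13 for AbPP antisense minus Random antisense, and App in Random antisense minus untreated SAMP8 was -0.00690. With only the 8 samples compared, SAMP8 minus Control gave 37, AbPP antisense minus Random antisense 0 and AbPP antisense minus untreated SAMP8 5, and the share, an added alternative, was 43.2%. Taking Random antisense or AbPP antisense minus untreated SAMP8 as the treatment change, which shares the SAMP8 arrays with the line difference, gave shares of 59.3% and 56.98%. With the SAMP8 arrays parted between the changes in 6 ways, for the same calls, the mean shares were 57.2% and 55.2%. Values simulated with neither a line difference nor a reversal gave 72.8% and 59.9%. Those are no baseline for the real calls, whose line difference had a mean size of 1.91, so no conclusion is drawn.

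Added alternatives leave out arrays or adjust for RNA quality. Without Control 4 and AbPP antisense 4, AbPP antisense minus Random antisense gave 199, AbPP antisense minus untreated SAMP8 401, AbPP antisense minus Control 1182, Random antisense minus Control 184 and the F test 480. App in SAMP8 minus Control was -0.0525, and the interferon and microglia lists in SAMP8 minus Control had medians of 0.0486 and 0.149, of opposite sign to those with all arrays. Without the 3 arrays of lowest weight the counts were 164, 1990, 0, 2005, 3230, 402 and 2090, and App in SAMP8 minus Control was again -0.0525. With the beta-actin 3' to 5' difference as a covariate, AbPP antisense minus Random antisense gave 59 and AbPP antisense minus Control 308, and App fell outside its leave-one-out range, at -0.124 in AbPP antisense minus Random antisense and -0.0920 in AbPP antisense minus untreated SAMP8.

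Of 9, 14, 10 and 11 gene lists called in the 4 comparisons, an estimated correlation kept 0, 1, 0 and 1 fry called 0, 3, 0 and 2, and the mean of all probe sets of a gene called 9, 12, 9 and 12; without Control 4 and AbPP antisense 4, 3 were called in SAMP8 minus Control. Leaving out 1 array in turn gave 54 to 115 for SAMP8 minus Control, 11 to 896 for AbPP antisense minus Random antisense, 16 to 1286 for AbPP antisense minus untreated SAMP8, 309 to 2616 for AbPP antisense minus Control, 62 to 149 for Random antisense minus Control and 117 to 963 for the F test. Random antisense minus untreated SAMP8 stayed at 0. The share reversed ran from 38.8% to 59.3% and the move from -0.0476 to 0.0600. In all 33 alternatives the smallest exact permutation p of the move was 0.0571, and 22 had the opposite sign. With 1 array left out in turn, App ran from -0.05 to 0.12 in SAMP8 minus Control, from -0.27 to -0.13 in AbPP antisense minus Random antisense and from -0.25 to -0.10 in AbPP antisense minus untreated SAMP8.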

Other observations

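The tests in this part were chosen only after the result was seen. Of the 54 genes called between the lines by any probe set, the 3 chromosomes with most of them held 12, 8 and 8, where 3.30, 3.17 and 1.76 would lie there in proportion to the genes tested. Whether chance gives such counts was not tested.

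Habenula markers, a list written after the arrays were seen, had scores of -2.01, 0.71, -1.34 and 0.23 on AbPP antisense 1 to 4, where thalamus had -1.46, -0.10, -1.34 and 0.36. Choroid plexus was lowest on AbPP antisense 2 (-1.53), which was not low in habenula and little below 0 in thalamus. AbPP antisense 1 and 3, low in thalamus and habenula, were also low in choroid plexus (-0.70 and -1.16). Ttr, made by choroid plexus, read 13.26, 10.84, 13.45 and 15.28 on the AbPP antisense arrays and 15.27 to 15.74 on the Random antisense arrays. Thalamus scores differed outside the AbPP antisense group too. They were 0.22 to 0.34 in untreated SAMP8 and -0.37 to 0.14 after Random antisense (exact permutation p = 0.0286, not adjusted). In Control they were 0.52, 0.62, 0.49 and -0.33. The share of neighbouring tissue in each dissection may therefore have differed between mice of all groups. For the AbPP antisense arrays, a median ratio of 0.566 on AbPP antisense 4 leaves this open.

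S100a8 (3.79) and S100a9 (3.38), neutrophil genes, and Alas2 (2.25) and Slc4a1 (1.94), erythrocyte genes, had positive differences in AbPP antisense minus Random antisense. None passed, with adjusted p = 0.0588 over the list alone. Meninges markers were also low on AbPP antisense 2, with a score of -1.49.

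Gnb1 and Cap1 varied between AbPP antisense mice: Gnb1 read 11.94, 12.03, 10.83 and 12.50, and Cap1 read 6.57, 6.69, 7.89 and 6.19, in the same order of arrays. On AbPP antisense 3 both lay near the untreated SAMP8 mean (10.76 and 7.88). The residual spread of the arrays relative to the average ran from 1.24 to 1.99 after AbPP antisense and from 0.37 to 0.51 in the untreated SAMP8 and Random antisense arrays.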
